A study of Mus musculus with 8 samples.

How the data were processed

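Antigen-experienced conventional CD4 T cells (CD44 positive, Foxp3 reporter negative, TCRβ positive, CD11b negative) were sorted from the brain without its meninges and from the spinal cord of Foxp3-Cre-YFP reporter mice with experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis, per the labels' protocols. Single-cell RNA and 3 surface proteins (CD69, the ATP receptor P2X7 and the chemokine receptor CXCR6) were read by CITE-seq, which tags antibodies with DNA barcodes so that bound antibody is counted beside RNA in each droplet. There was 1 RNA library and 1 antibody library for each tissue at day 14 and at day 50 after immunization, 8 GEO samples in 4 groups of cells. The labels do not state how many mice each library holds.

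The deposited values are raw UMI counts per barcode, in 1 matrix per RNA library with gene features and 3 antibody features, per the file headers. The counts were made with Cell Ranger 6.1.1 on the mm10 build, per the submitters' processing notes, and the barcodes had already been called as cells before deposit. Nothing had been normalized. The antibody samples had no files of their own; their counts are the antibody features of the matrices. Those features carry an identifier and a name, and for 2 of the 3 these differ: the identifiers read CD69, P2X7R and CXCR6, and the names read CD69, CD3 and CD16. The identifiers were used, because the labels name these proteins and the counts follow the transcripts: in the day 14 spinal cord library the median P2X7R count was 25 in cells with a P2rx7 UMI and 7 in cells without, and the median CXCR6 count was 26 with and 9 without a Cxcr6 UMI.

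The choices named in this and the following paragraphs were made before the data were examined unless stated otherwise. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, Scrublet (in scanpy 1.11.5) was run per library at an expected rate of 0.8% per 1000 barcodes, and its 15 calls in the day 50 brain library and 15 in the day 50 spinal cord library were removed. Scrublet called 0 doublets in both day 14 libraries, which under the rule set for libraries of over 5000 barcodes counts as a failure, so doublets stayed in there. Every cluster held T cell receptor or CD3 transcripts in at least 99.9% of cells and none was named as another cell type, so no cells were removed as non-T cells and no cell type was at hand to measure free RNA against. Kept cells numbered 10313 in brain at day 14, 333 in brain at day 50, 9270 in spinal cord at day 14 and 1605 in spinal cord at day 50.

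Counts were summed per library and gene and scaled by the library's sum to CPM. Each level carries an exact Poisson 95% interval and each ratio the exact conditional binomial 95% interval; both cover counting error only. With 1 library per group no test across animals was possible, cells are not replicates, and no p-value is given. No paired analysis was possible because each group is a single library and the labels do not pair tissues by mouse. Genes with at least 10 UMIs over the 2 libraries were compared, and a gene is called higher or lower where its ratio is at least 1.5-fold and its interval excludes 1. A gene at 0 counts was set against a floor of 3 counts per library, which is 0.0635 CPM in brain at day 14, 2.69 in brain at day 50, 0.0592 in spinal cord at day 14 and 0.499 in spinal cord at day 50. The genes named are, for each comparison, the 10 higher and 10 lower genes whose interval lies farthest from 0 among genes at 50 CPM or more, up to 4 members of each list by the same measure, and 15 focal genes of residency, recirculation and effector type; 4 of these genes are not reported here, though they stay in all sums, lists and counts. The 20 gene lists were residency, egress and lymph node homing, Th1, Th17, Th2, effector cytokines and chemokines, Tfh, inhibitory receptors, cytotoxic, proliferation, interferon response, TCR activation, immediate early and heat shock, glycolysis, oxidative phosphorylation, lipid handling, survival, chemokine receptors and integrins, TGF-beta, and regulatory T cell. A list is described by the median log2 ratio of its measured members, a 95% interval from 1000 Poisson draws, and its percentile among 10000 random lists matched on expression in 20 bins.

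The median log2 ratio over all compared genes was -0.06 for day 50 against day 14 in brain, -0.31 for the same days in spinal cord, 0.20 for spinal cord against brain at day 14 and 0.03 at day 50. Where it passed 0.1 in size, ratios in the report are given after subtracting it, with the calls made again on the shifted values.

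Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, with exact Clopper-Pearson 95% intervals. Antibody gates were set per library at the crossing of a 2-component Gaussian mixture of log counts (scikit-learn 1.9.0). The plan asked for no gate where the components are not separated but gave no limit. The rule used, that a crossing exists and the lower component has a mean above 0.5 counts, was chosen after the fits had been seen, when a stricter rule (Ashman's D, a measure of separation, above 2) had also been considered; D ran from 1.65 to 2.76 over the 9 gates used of 12 fitted. No gate was set in the day 50 brain library, where the lower component sat at 0 counts for all 3 antibodies. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden at resolution 1 (igraph 0.11.9) with no batch correction. The limits for describing a cluster (1.5-fold, detection in 10% of cells, 20 CPM added to both sides) were chosen after the data had been seen, as were the transcripts outside the focal genes that are set against the antibodies.

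The ratio and list calculations were tested on simulated Poisson counts drawn from the pooled mean of the libraries compared, with 200 changed genes per comparison. A true 2-fold change was called in 67.4% of 86 genes for the days in brain (11307 genes run), 81.2% of 96 in spinal cord (12778 genes), 94.9% of 99 for the tissues at day 14 (13668 genes) and 63.2% of 95 at day 50 (10012 genes). Between 0.884% and 2.22% of unchanged genes were called. The simulation held counting error only, with no variation between cells or animals. These rates therefore check the calculation and are not the false-call rates of the real libraries. Alternatives covered normalization, weight of cells, thinning, filters, doublets, cycling cells, Foxp3 UMIs, gates, thinning depth, cluster resolution and centring per library. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.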

Results

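Conventional CD4 T cells that had met antigen were profiled from brain and spinal cord in EAE, early in disease at day 14 and in its chronic phase at day 50. The series asks what part tissue-resident memory CD4 T cells, which stay in a tissue without recirculating, play in chronic disease of the central nervous system. Each of the 4 groups was 1 RNA library with its antibody counts, so there were no replicates, and every difference below is between single libraries. The kept cells held 47272714 RNA UMIs in brain at day 14 and 1115291 at day 50, and 50710551 in spinal cord at day 14 and 6017616 at day 50. The median cell held 4004, 2950, 4921 and 3467 UMIs in that order, and 1353, 1087, 1716.5 and 1225 genes. Antibody UMIs totalled 410513, 5082, 621617 and 61218 over the deposited barcodes.

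Transcripts of other lineages were counted in each library, in the order brain day 14, brain day 50, spinal cord day 14 and spinal cord day 50. Foxp3, the lineage factor of regulatory T cells, had 2, 0, 1 and 1 UMIs, Cd8a 1, 0, 8 and 0, and Cd8b1 251, 4, 328 and 30. Markers of B cells summed to 50.9, 75.3, 27.4 and 91.1 CPM and those of gamma-delta T cells to 8.19, 10.8, 6.59 and 20.4 CPM; in spinal cord 2 of 3 B cell markers and 4 of 4 gamma-delta markers measured were higher at day 50. The Y-linked gene Ddx3y lay between 64.9 and 84.3 CPM and Xist had at most 9 UMIs, so the cells came from male mice. Markers of dendritic cells summed to 102 CPM in brain at day 50 against 11.1 to 15.1 CPM in the other libraries; 56 of the 63 UMIs of Cd74, the invariant chain of MHC class II, came from 1 cell. Ribosomal protein genes took 34.1% of UMIs in brain at day 14, 36.3% in brain at day 50, 30.8% in spinal cord at day 14 and 37.6% in spinal cord at day 50.

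The antibodies mark surface proteins used to recognise resident cells: CD69, which opposes exit from tissue, CXCR6 and P2X7. Their genes lie on 3 chromosomes of the mm10 build (coordinates from the GRCm38.p6 annotation): Cd69 on chromosome 6 from 129267324 to 129275375, Cxcr6 on chromosome 9 from 123806477 to 123811754 and P2rx7 on chromosome 5 from 122643927 to 122692336. After thinning to 2000 UMIs, Cd69 was detected in 60.8% of brain cells at day 14 (95% interval 59.8 to 61.8) and 63.7% at day 50 (57.2 to 69.8), and in 46.9% (45.9 to 47.9) and 34.4% (31.9 to 36.9) of spinal cord cells. Cxcr6 was detected in 41.2% (40.2 to 42.2) and 39.7% (33.4 to 46.2) of brain cells and in 59.0% (57.9 to 60.0) and 37.2% (34.7 to 39.7) of spinal cord cells. P2rx7 was detected in 4.82% (4.39 to 5.28) and 2.95% (1.2 to 5.99) of brain cells and in 8.37% (7.81 to 8.96) and 6.56% (5.35 to 7.95) of spinal cord cells. All 3 transcripts together were found in 1.49% (1.25 to 1.76), 2.11% (0.688 to 4.85), 2.60% (2.28 to 2.94) and 1.15% (0.671 to 1.84) of cells, in the order brain day 14, brain day 50, spinal cord day 14 and spinal cord day 50. Thinning left out 1163, 96, 142 and 127 shallower cells in that order. No cell type lacking these genes was present, so the part of such shares that free RNA gives is unknown.

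**Figure D1:**
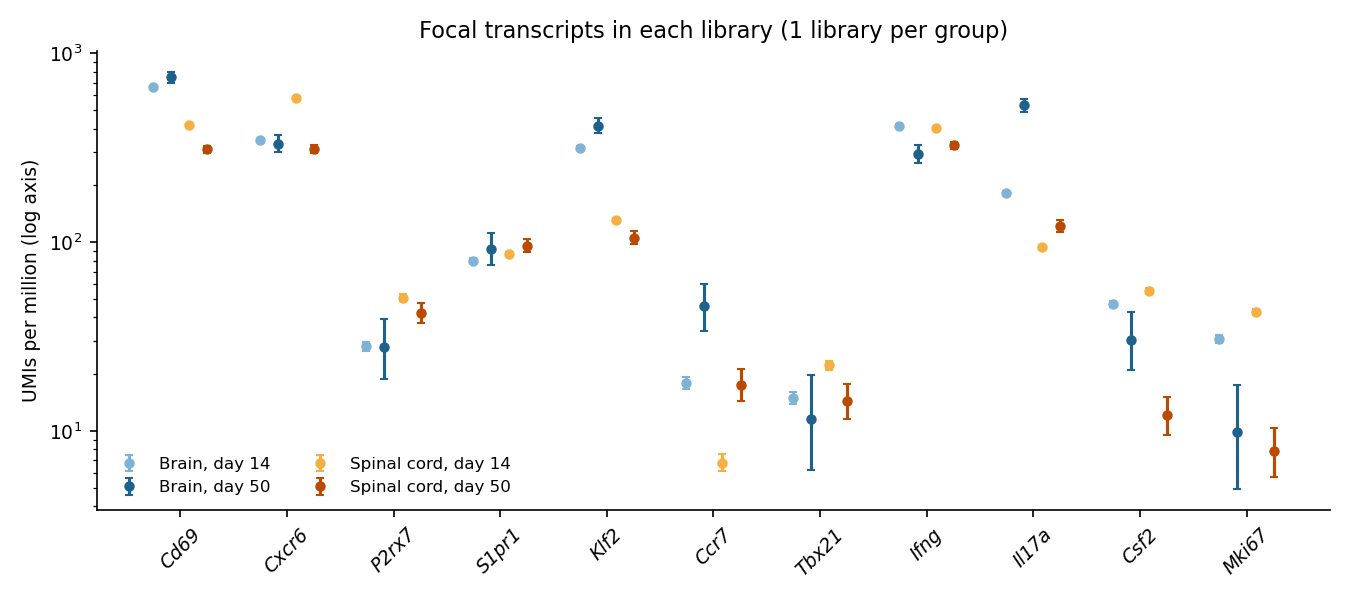
Levels of focal transcripts in the 4 libraries, in CPM on a log axis, with exact Poisson 95% intervals that cover counting error only; Foxp3 and Itgae, near the floor, are not drawn, nor are focal genes not reported here. Il17a stood highest in brain at day 50 (531 CPM), and Csf2 stood lowest in spinal cord at day 50 (12.1 CPM).

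The first comparison asks how T cells in the brain differ between chronic and early disease. At day 50 the brain library held more Il17a, the cytokine of Th17 cells, which rose 2.92-fold from 182 to 531 CPM (log2 1.54, interval 1.42 to 1.66). Of the immediate-early genes, switched on within minutes of a stimulus, Atf3 rose 6.99-fold, Egr1 4.12-fold, Fos 2.17-fold and Junb 1.84-fold. Eomes, a transcription factor of cytotoxic and memory T cells, rose 7.25-fold, while the granzyme genes Gzma and Gzmb, which encode killing proteases, fell by 3.63 and by 2.01 on the log2 scale. Il22, a Th17 cytokine that acts on epithelia, went from 86.1 to 5.38 CPM (6 UMIs at day 50), and Mki67, a marker of dividing cells, fell by 1.64 on the log2 scale.

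Of 17 measured immediate early and heat shock genes 8 were higher and 0 lower at day 50, with a list median of 0.54 (0.47 to 0.67, percentile 100 among the matched random lists). The proliferation list had 1 member higher and 11 lower of 26 (median -0.54, interval -0.88 to -0.42, percentile 0.01), among them Ccnb2 at -3.26 (3 UMIs at day 50, interval -5.54 to -1.71), Rrm2 at -1.60 and Stmn1 at -1.51. Residency genes had 7 higher and 0 lower of 20 (median 0.20, interval 0.13 to 0.51, percentile 99.4): Ccr8, a chemokine receptor, rose 3.89-fold, the collagen-binding integrin gene Itga1 2.84-fold, Rgs2 1.92-fold and Rgs1 1.63-fold. The antibody targets were not among those called: Cd69 had a log2 ratio of 0.17, Cxcr6 of -0.06 and P2rx7 of -0.02. Cytotoxic genes had 3 higher and 5 lower of 12 (median -0.41), with Fasl, a death ligand, 2.10-fold higher. The interferon-induced membrane genes Ifitm1, Ifitm2 and Ifitm3 fell by 3.39, by 1.97 and by 1.85, whereas the interferon response list had 1 higher and 1 lower of 23 (median 0.04).

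Th17 genes had 5 higher and 3 lower of 12 (median -0.22); Il17f stood at -2.75 with 3 UMIs at day 50 (interval -5.03 to -1.2) and Ccl20, a chemokine of Th17 cells, at 3.99 with 3 UMIs at day 50 (1.44 to 6.05). Th1 genes had 2 higher and 1 lower of 12 (median -0.13): Ccl5 rose 1.55-fold, and Ifng, the Th1 cytokine, had a ratio of -0.50. Effector cytokines and chemokines had 3 higher and 3 lower of 14 (median 0.23), with Ccl4 2.52-fold higher and Csf2, which encodes GM-CSF, 0.647-fold. TCR activation genes had 6 higher and 1 lower of 17 (median 0.19), including Cd40lg, the ligand T cells use to help other immune cells, at 2.67-fold, and Il2ra at -1.42. Tfh genes had 2 higher and 2 lower of 8 (median 0.70), inhibitory receptors 2 and 3 of 10 (0.22), egress and lymph node homing 1 and 3 of 11 (-0.14), Th2 genes 0 and 0 of 4 (0.02) and regulatory T cell genes 1 and 1 of 7 (-0.37). Among egress genes Ccr7, the lymph node homing receptor, rose 2.54-fold. Glycolysis had 2 higher and 2 lower of 16 (-0.33), oxidative phosphorylation 1 and 2 of 22 (-0.22), lipid handling 0 and 1 of 11 (-0.17), survival 0 and 0 of 11 (-0.04), chemokine receptors and integrins 0 and 1 of 14 (-0.24) and TGF-beta 1 and 1 of 7 (-0.26).

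Other genes at the top were Ier5l (7.72-fold), Penk (3.99-fold), Snhg9 (3.58-fold) and Vps37b (2.62-fold), and among the lowest Plac8 (-2.42), Cd160 (-2.37) and Lgals3 (-1.57). The day 50 brain library is small, with 333 cells, and a few cells decide some values: 2 cells held 20.4% of its Il17a UMIs, 51.4% of Penk, 62.5% of Gzmb and 72.7% of the 11 UMIs of Mki67, and in brain at day 14 they held 62.1% of Il17f UMIs. Without the 2 richest cells per gene, the Cd74 log2 ratio goes from 2.5 to -1.09, that of Mki67 from -1.64 to -3.48, that of Gzmb from -2.01 to -3.34, the Tfh median from 0.70 to -0.01 and the residency median from 0.20 to 0.09, while the median of all compared genes itself goes from -0.06 to -0.35.

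The second comparison asks the same of the spinal cord. There the median of all compared genes lay at -0.31, so the log2 ratios of this comparison are relative to it unless stated otherwise. Gzmk, a granzyme of memory-like T cells, stood 2.98 higher at day 50 (26.7 to 170 CPM), Eomes 3.79 higher and the chemokine gene Ccl5 2.18 higher (900 to 3288 CPM). Genes linked to Th17 cells went both ways: the interleukin 1 receptor gene Il1r1 stood at -2.63 and Csf2 at -1.87, while Il17a at 0.68 and Il17f at 2.61 were called higher. At 2000 UMIs the share of cells with an Il17a UMI went the other way, from 4.72% (4.30 to 5.18) to 2.64% (1.88 to 3.59). Mki67 stood at -2.14, and Havcr2 and Pdcd1, which encode the inhibitory receptors TIM-3 and PD-1, at -3.14 and -1.48.

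Proliferation genes had 0 members higher and 16 lower of 26 (relative median -0.70), with Cenpe at -1.75 and Mcm3 at -1.16. Glycolysis had 0 higher and 5 lower of 16 (-0.40), including the glucose transporter gene Slc2a3 at -1.43 and the lactate transporter gene Slc16a3 at -1.39. Th17 genes had 2 higher and 5 lower of 12 (-0.34). Residency genes had 7 higher and 2 lower of 21 (0.42): Rgs2 stood at 2.67, Xcl1 at 1.84 and Rgs1 at 1.28, while Cxcr6 was lower (-0.59) and Cd69 (-0.12) and P2rx7 (0.04) were not called. Interferon response genes had 10 higher and 2 lower of 23 (0.39), with Ifi27l2a at 1.37 and Rtp4 at 1.15. Immediate early and heat shock genes had 8 higher and 4 lower of 17 (0.23), with Atf3 at 3.42, Ier3 at 2.39 and Junb at 2.10. The heat shock gene Hspa1a stood at -3.50 over 1 UMI at day 50 (-3.81 before the all-gene median is subtracted, interval -9.12 to -1.30). Inhibitory receptors had 4 and 4 of 11 (0.38), with Tox at 1.92 and Ctla4 at 1.54, and cytotoxic genes 4 and 4 of 13 (0.23), with Gzma at -2.95. Tfh genes had 3 higher and 2 lower of 8 (0.62), with the folate receptor family gene Izumo1r at 2.42 and Bcl6, the Tfh lineage factor, at -1.47. TCR activation genes had 6 and 5 of 17 (0.06), with Egr2 at -2.37 and Il2ra at -1.76. Effector cytokines and chemokines had 5 and 5 of 14 (-0.09), with Spp1 at 2.59 and Ccl1 at -1.93. Egress and lymph node homing genes had 2 and 2 of 11 (0.33), with Ccr7 at 1.68 and Klf2, which drives exit receptors, at -0.00. Before the all-gene median is subtracted, the egress list had 2 higher and 3 lower (0.018, interval -0.17 to 0.10). On that scale its median was negative when cells were thinned to equal depth before summing.

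Th1 genes had 4 higher and 2 lower of 12 (-0.12); Tbx21, the Th1 lineage factor, stood at -0.32 and Ifng at 0.00, neither called. Th2 genes had 2 and 2 of 6 (-0.03), with Il4 at 5.38, survival genes 1 and 0 of 11 (0.29), with Cd27 at 2.02, and regulatory T cell genes 3 and 2 of 7 (0.49), with Ikzf2 at 1.84. Chemokine receptors and integrins had 2 and 5 of 15 (-0.23), TGF-beta 0 and 1 of 8 (-0.27), lipid handling 0 and 4 of 12 (-0.11) and oxidative phosphorylation 1 and 0 of 22 (0.17). The remaining genes at the extremes were Ier5l (4.27), Vps37b (3.11), Odc1 (2.39), Dusp10 (2.29) and St3gal6 (2.23) on the higher side, and Il1r2 (-3.04), Ifitm1 (-2.97), Ddit4 (-2.87), Ermn (-2.54), Cd160 (-2.41), Hist1h1b (-2.39), Nrgn (-2.30) and Ly6g5b (-2.27) on the lower side. In the day 50 library 2 cells held 63.9% of Il17f UMIs, 78.9% of Gzma, 81.7% of Ifitm1, 52.9% of Spp1, 58.1% of Ccl1 and 54.5% of Cenpe UMIs. Without subtracting the all-gene median, Il17a at 0.37 is not called higher and Tbx21 at -0.62 is called lower. On that scale Th1 genes had 2 higher and 5 lower (-0.43), interferon response genes 5 and 5 (0.079) and TCR activation genes 3 and 6 (-0.25). Inhibitory receptors had 2 and 5 (0.069), residency genes 5 and 3 (0.11, interval -0.037 to 0.22) and immediate early and heat shock genes 6 and 5 (-0.074). Proliferation genes had 0 and 21 there, glycolysis 0 and 9 (-0.71), chemokine receptors and integrins 2 and 7 (-0.54) and TGF-beta genes 0 and 4 (-0.58).

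Across 2654 genes at 50 CPM or more, the change with time in brain and in spinal cord had a Pearson correlation of 0.65 and a Spearman correlation of 0.60, and of 261 genes beyond 1.5-fold in both tissues 258 went the same way. The correlation is across genes, which are not independent replicates. Eomes, Atf3, Ier5l, Ccl5 and Ikzf2 were higher and Mki67, Gzma, Ifitm1, Cd160 and Il2ra lower at day 50 in both tissues.

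**Figure D2:**
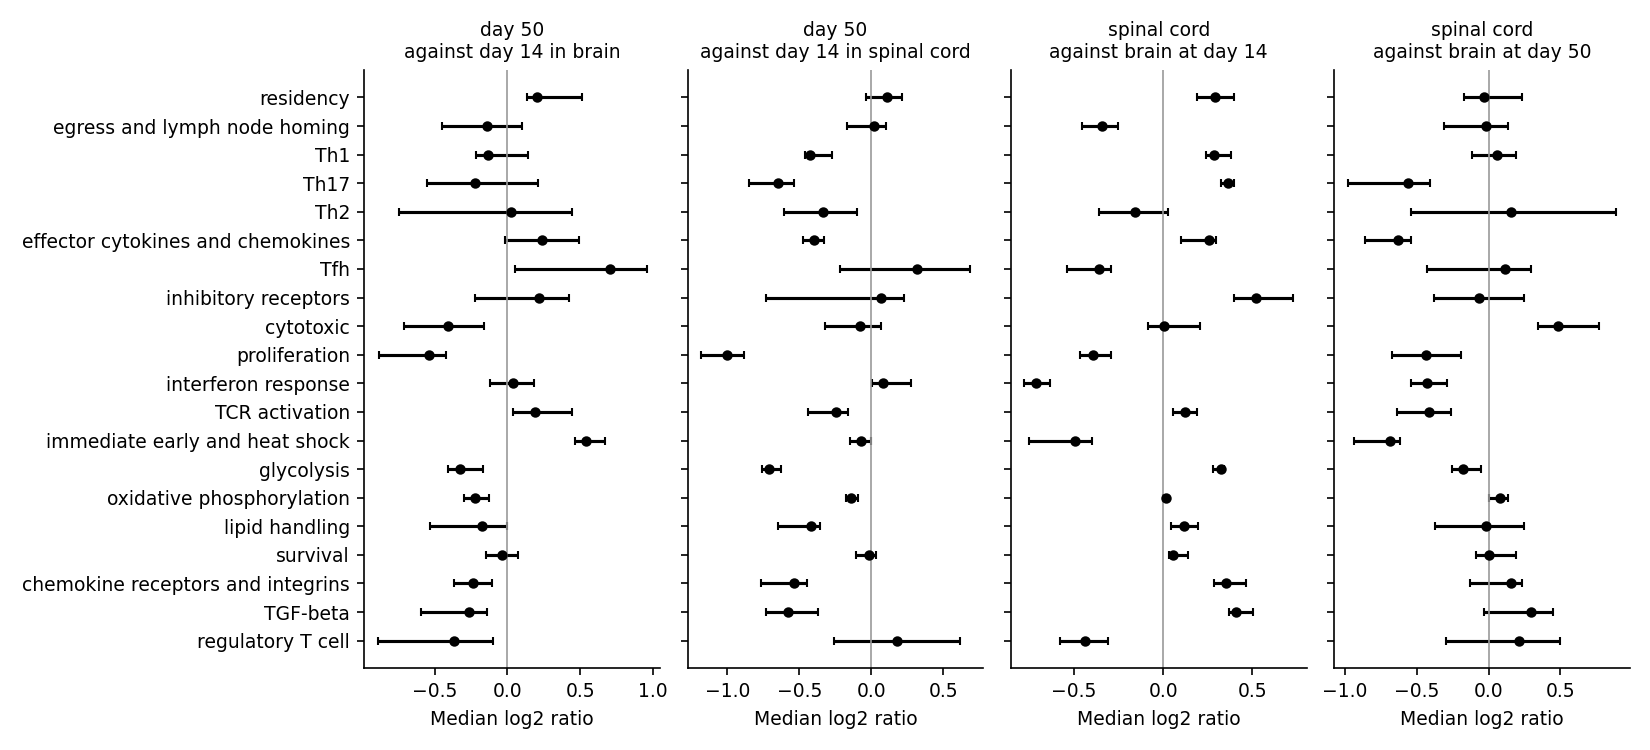
Median log2 ratio of each of the 20 gene lists in the 4 comparisons, before any all-gene median is subtracted; bars are 95% intervals from 1000 Poisson draws and cover counting error only. Proliferation lay at -0.54 in brain and -1.0 in spinal cord from day 14 to day 50, and immediate early and heat shock genes at -0.50 and -0.69 in spinal cord against brain.

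The third comparison sets spinal cord against brain at day 14. The median of all compared genes was 0.20, and log2 ratios here are relative to it. Of the genes of recirculating cells, Klf2 (-1.48) and Ccr7 (-1.60) were lower in spinal cord, while S1pr1 (-0.084) was not called. P2rx7 (0.65) and Itga1 (1.06) were higher, Cxcr6 at 0.54 was short of the 1.5-fold limit (0.74 and called higher before subtraction), and Cd69 was lower (-0.88). Among interferon response genes Ifi27l2a stood at -1.75, Rsad2 at -1.57, Ifit3 at -1.55 and Isg15 at -1.42. Il1r1 (0.86) was higher, whereas the cytokine genes Il17a (-1.15), Il17f (-2.52, with 62.1% of its brain UMIs in 2 cells) and Il22 (-1.60) were lower.

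Interferon response genes had 0 members higher and 14 lower of 23 (relative median -0.91), immediate early and heat shock genes 1 and 10 of 17 (-0.70), with Atf3 at -1.96, Zfp36 at -1.69 and Dusp1 at -1.62, and egress and lymph node homing genes 0 and 5 of 11 (-0.54). Proliferation had 0 higher and 13 lower of 26 (-0.59), with Ube2c at -1.45 and Birc5 at -1.30, while Mki67 stood at 0.27; without cycling cells the list median moves from -0.39 to 0.08 before the all-gene median is subtracted. Residency genes had 4 higher and 2 lower of 21 (0.09), with Inpp4b at 0.68 and Rgs2 at -1.40. Inhibitory receptors had 3 and 2 of 11 (0.32): Havcr2 stood at 1.18, Entpd1 at 0.72 and Lag3 at 0.59, against Ctla4 at -1.64. Th17 genes had 4 and 3 of 12 (0.16), Th1 genes 2 and 1 of 12 (0.09), with Il12rb2 at 0.91, and TCR activation genes 3 and 4 of 17 (-0.08), with Egr2 at 1.46 and Nr4a1 at -1.26. Effector cytokines and chemokines had 1 and 4 of 14 (0.06), with Lta at 0.73 and the anti-inflammatory cytokine gene Il10 at -2.10. Cytotoxic genes had 0 and 3 of 13 (-0.20), with Gzmk at -1.28, and Tfh genes 1 and 4 of 8 (-0.56), with Izumo1r at -1.40 and Bcl6 at 0.60. Regulatory T cell genes had 2 and 4 of 8 (-0.64). Before subtraction, thinning cells to 2000 UMIs moved that list's median from -0.44 to 0.16, which was still below the all-gene median of 0.22 after thinning. Lrrc32 had 0 UMIs in spinal cord and was at least 6.08-fold lower before the all-gene median is subtracted. Chemokine receptors and integrins had 3 and 1 of 15 (0.15), with Cxcr4, the receptor of CXCL12, at -2.39 and Itgb1 at 0.62. Glycolysis had 1 and 0 of 16 (0.13), TGF-beta 1 and 0 of 9 (0.21), Th2 genes 0 and 2 of 6 (-0.36), lipid handling 0 and 1 of 12 (-0.08), survival 0 and 2 of 11 (-0.14) and oxidative phosphorylation 0 and 0 of 22 (-0.18). Without subtraction residency genes had 7 higher and 2 lower (0.29), inhibitory receptors 5 and 2, effector cytokines and chemokines 3 and 4 and TCR activation genes 4 and 3. Lipid handling genes had 2 and 0 there, glycolysis 3 and 0, proliferation 0 and 7, interferon response 0 and 12 and immediate early and heat shock genes 1 and 8. Genes at the extremes also included Apol7e (1.53), Kcnq1ot1 (1.37), Mdfic (1.02), Hist1h1e (0.99) and Rbpj (0.98), and Tsc22d3 (-1.68), Csrnp1 (-1.54) and Gadd45b (-1.47).

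The fourth comparison sets spinal cord against brain at day 50. Il17a was lower in spinal cord, with a log2 ratio of -2.13 (122 against 531 CPM), and so were Csf2 (-1.33) and the chemokine receptor gene Ccr6 (-1.89). Of the genes of cytotoxic cells, Nkg7 was 1.75-fold higher, Klrd1, a receptor of natural killer and cytotoxic cells, 1.78-fold, Gzmk 1.53-fold and Gzmb 2.17-fold, the last over 16 UMIs in brain with 62.5% in 2 cells and 43.9% of the spinal cord UMIs in 2 cells. The chemokine gene Xcl1, of the residency list, was 2.74-fold higher. Klf2 (-1.97) and Ccr7 (-1.38) were lower, as was Cd69 (-1.27), while Cxcr6 (-0.10) was not called. In brain 2 cells held 31.4% of the Ccr7 UMIs. P2rx7 was 1.52-fold higher, and falls short of the limit once the all-gene median of 0.03 is subtracted.

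Cytotoxic genes had 4 members higher and 0 lower of 11 (median 0.49, interval 0.35 to 0.77). Immediate early and heat shock genes had 0 higher and 9 lower of 15 (-0.69, interval -0.94 to -0.62), with Zfp36 at -2.40, Fos at -2.31, Fosb at -1.77 and Atf3 at -1.45. Effector cytokines and chemokines had 2 and 8 of 14 (-0.63, interval -0.86 to -0.54), with Ccl4 at -1.51, Lta at -1.34 and Il2 at -1.10, which rests on 2 cells that held 77.0% of its UMIs in brain. Th17 genes had 2 and 5 of 11 (-0.56, interval -0.98 to -0.41); Il17f stood at 2.74 over 3 UMIs in brain (1.15 to 5.04). TCR activation genes had 0 and 6 of 17 (-0.42), with Irf4 at -1.49 and Nr4a1 at -1.39, and interferon response genes 0 and 6 of 22 (-0.43), with Isg15 at -0.93 and Ifi27l2a at -0.91. Proliferation had 0 and 6 of 26 (-0.44), which rests on few cells: 2 cells held 97.9% of Ube2c UMIs in brain, and without the 2 richest cells per gene the median moves to 0.29 and Ube2c from -3.05 to 1.15. Residency genes had 3 and 1 of 20 (-0.03), egress and lymph node homing 1 and 2 of 11 (-0.02), Th1 genes 0 and 0 of 12 (0.06), Th2 genes 1 and 0 of 5 (0.15), Tfh genes 0 and 2 of 7 (0.11), inhibitory receptors 0 and 1 of 10 (-0.07) and regulatory T cell genes 0 and 2 of 7 (0.21). Il4 had 0 UMIs in brain and was at least 2.22-fold higher in spinal cord. Glycolysis had 0 and 1 of 16 (-0.18), oxidative phosphorylation 0 and 0 of 22 (0.08), lipid handling 1 and 0 of 11 (-0.02), survival 0 and 0 of 11 (0.01), chemokine receptors and integrins 0 and 1 of 13 (0.15) and TGF-beta 0 and 0 of 7 (0.29). Other genes at the extremes were Plac8 (1.47) and Tbc1d4 (0.97), and Klf6 (-1.53), Tagap (-1.82) and Cd74 (-2.98, or 0.25 without the 2 richest cells). Across 2654 genes the tissue difference at day 14 and at day 50 had a Pearson correlation of 0.17 and a Spearman correlation of 0.04, and 39 of 57 genes beyond 1.5-fold at both days went the same way.

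Surface protein was read within each library. With gates set per library, CD69 marked 17.9% of brain cells at day 14 (17.1 to 18.6), 34.6% of spinal cord cells at day 14 (33.6 to 35.5) and 49.5% at day 50 (47.1 to 52.0). P2X7 marked 28.4%, 37.5% and 54.3%, and CXCR6 51.7%, 76.2% and 68.7%, in the same order. Cells positive for all 3 made up 7.41% (6.91 to 7.93), 17.5% (16.7 to 18.3) and 30.8% (28.5 to 33.1), against 2.62%, 9.88% and 18.5% if the 3 proteins were independent. The antibody counts were not scaled per cell, so differences between cells in total counts can also raise the joint share. Doublets, which were not removed from the day 14 libraries, can do the same there. Their expected rates were 8.59% in brain and 7.59% in spinal cord. Neither part was separated. The order of the spinal cord days depends on the gate: with 1 gate over all libraries the share was 21.8% at day 14 and 12.8% at day 50, and 5.74% and 1.2% in brain. Median counts of CD69, P2X7 and CXCR6 were 4, 5 and 13 in brain at day 14, 1, 1 and 3 in brain at day 50, 9, 9 and 22 in spinal cord at day 14 and 4, 7 and 11 in spinal cord at day 50.

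**Figure D3:**
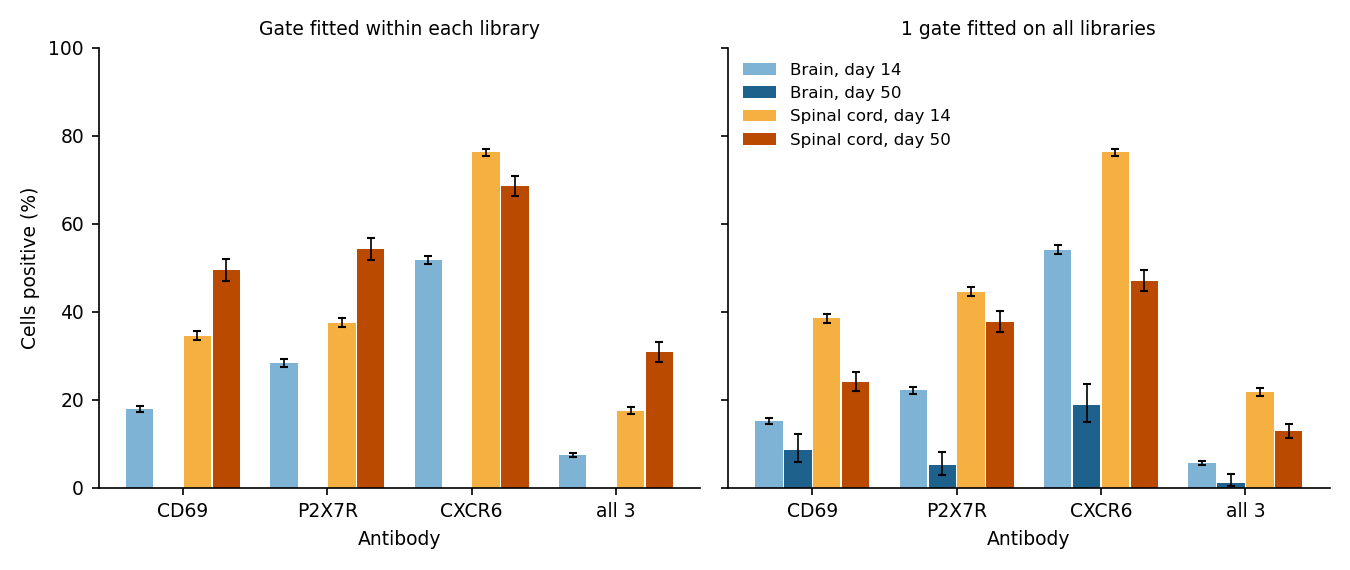
Percent of cells positive for each antibody and for all 3, with gates fitted within each library (left; no gate could be set for brain at day 50) and with 1 gate over all libraries (right); bars are exact 95% intervals that cover counting error only. All-3-positive cells in spinal cord were 17.5% at day 14 and 30.8% at day 50 on the left, and 21.8% and 12.8% on the right.

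Within each library, cells positive for all 3 proteins were set against cells positive for none. Cxcr6 RNA was higher by 1.28 in brain at day 14, 1.14 in spinal cord at day 14 and 2.06 at day 50 on the log2 scale, and P2rx7 RNA by 1.68, 1.99 and 1.55. Cd69 RNA was not called at day 14 (0.19 and 0.15) and was 0.77 higher in spinal cord at day 50. Of the genes of recirculation, Klf2 stood at -2.18, -3.03 and -2.90 and S1pr1, the exit receptor, at -2.15, -2.38 and -3.53. Egress and lymph node homing genes had 9 of 11, 10 of 11 and 8 of 11 members lower (medians -1.67, -2.38 and -1.29). At day 50 the list also had 2 members higher, among them Ly6c2 (13.4-fold). Residency genes had 6 of 20, 10 of 20 and 10 of 18 members higher (0.40, 0.65 and 0.70), with 1 lower in brain at day 14. That list holds Cd69, Cxcr6 and P2rx7, the genes of the gated proteins, so its result is not independent of the gates. Th17 genes were higher in 10 of 11, 6 of 11 and 4 of 8 members (1.62, 1.27 and 2.02). Csf2 was 1.90, 1.43 and 3.99 higher, the last over 1 UMI in the negative cells (interval 1.43 to 9.32), and Il17a 1.72 and 1.72 higher at day 14, while at day 50 it stood at 0.14 and was not called. Ifng was 0.82, 0.48 and 1.40 higher, of which the second was not called. Gzmk (-2.41, -3.20 and -2.05) and Eomes (-3.60, -4.18 and -2.64) were lower. Positive cells also held more UMIs, with medians of 6265 against 2897 in brain at day 14, 5947 against 3925.5 in spinal cord at day 14 and 4155.5 against 2721 at day 50.

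Clustering of all cells gave 12 clusters, whose sizes describe each library and are not compared between groups, since the genes that form them differ between libraries. Cluster 8, with leading genes Klf2 and Tcf7, held 22.3% (21.5 to 23.1) of brain cells at day 14, 24.6% (20.1 to 29.6) at day 50, 8.52% (7.96 to 9.11) of spinal cord cells at day 14 and 16.9% (15.1 to 18.9) at day 50. In it the share positive for all 3 proteins was 0.783% in brain at day 14, 1.14% in spinal cord at day 14 and 2.94% at day 50. Cluster 0, with leading genes Tff1, Ramp1 and Il1r1, held 7.55%, 1.80%, 19.0% and 0.374% of cells in the order brain day 14, brain day 50, spinal cord day 14 and spinal cord day 50, and 19.6% and 31.6% of its day 14 cells in brain and spinal cord were positive for all 3. Cycling cells (cluster 1) made up 5.19%, 1.2%, 3.18% and 0.685%, and interferon-responding cells (cluster 7) 7.92%, 5.11%, 3.65% and 2.43%. Cluster 11, with leading genes Gzmk, Ccl5, Eomes and Xcl1, held 0.815%, 30.3%, 0.464% and 50.0%; 802 of its 1030 cells came from the day 50 spinal cord, and a cluster mostly of 1 library may be that library. Of these 802 cells, 35.2% were positive for all 3 proteins, and of the 207 cells of cluster 3 in the same library 58.5%.

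**Figure D4:**
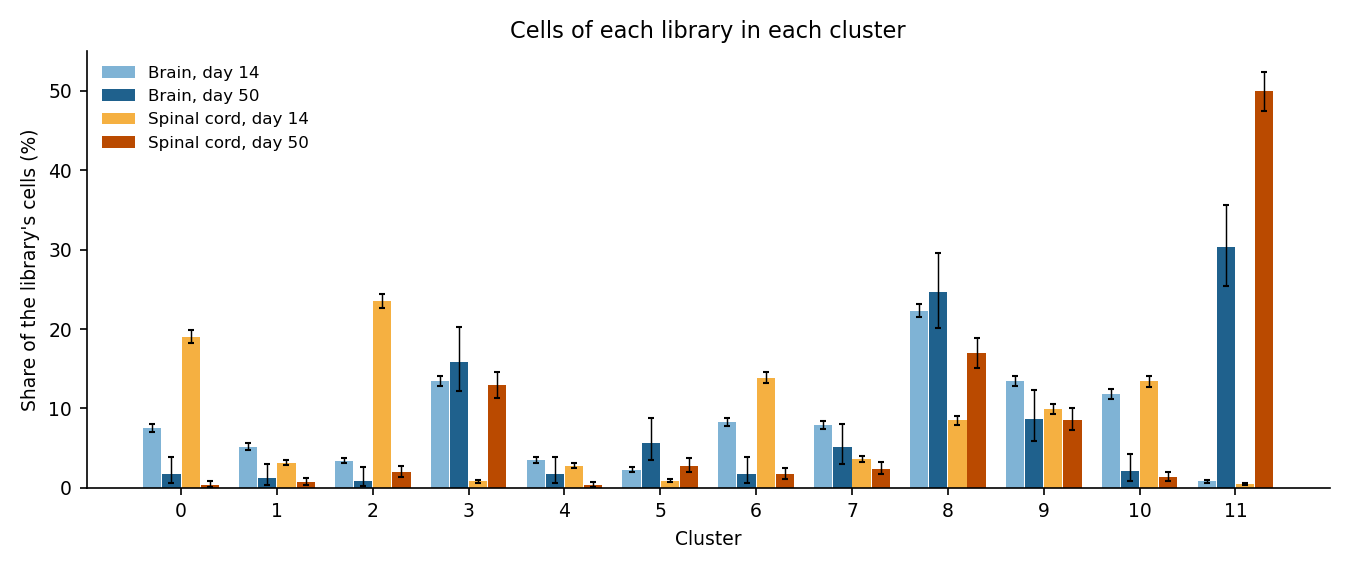
Percent of the cells of each library in each of the 12 clusters, with exact Clopper-Pearson 95% intervals that cover counting error only. Cluster 11 held 50.0% of day 50 spinal cord cells and 30.3% of day 50 brain cells, and under 1% of the cells of either day 14 library; after centring per library the nearest cluster held 21.9% and 16.2% at day 50 and 6.33% and 8.58% at day 14, spinal cord first.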

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

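The tests of other lymphocytes and of doublets were chosen after the result was seen, and the free RNA test before. The opposite changes listed first come from single libraries, and the differences were not tested.

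From day 14 to day 50, 5 of the named genes went opposite ways in the 2 tissues beyond 1.5-fold before an all-gene median is subtracted, and the spinal cord change minus the brain change is given in log2. It was 1.96 for Areg, which encodes a growth factor of tissue repair (lower in brain, higher in spinal cord), and 5.06 for Il17f (lower in brain, where 2 cells held 62.1% of its UMIs at day 14 and 3 UMIs were left, and higher in spinal cord, where 2 cells held 63.9% of its UMIs). It was -6.22 for Ccl20 (3 UMIs in brain at day 50, and 72.8% of those in spinal cord at day 14 in 2 cells), -1.42 for Tagap and -1.81 for Ube2c (2 cells held 97.9% of its UMIs in brain and 61.9% in spinal cord at day 50), which were higher in brain and lower in spinal cord; after the subtraction Tagap falls short of 1.5-fold in spinal cord. Areg had 26 UMIs in brain at day 50, and 2 cells held 30.8% of them.

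The tissues also ordered oppositely at the 2 days for the 18 genes named here, again before subtraction, and the spinal cord to brain ratio at day 50 minus that at day 14 is given in log2. Genes lower in spinal cord at day 14 and higher at day 50 were Areg (1.96), Gzmb (1.94, with 62.5% of brain and 43.9% of spinal cord UMIs at day 50 in 2 cells each), Gzmk (1.70), Il17f (5.06), Il22 (3.43, with 6 UMIs in brain at day 50 and 77.3% of the spinal cord UMIs in 2 cells), Il4 (3.33, with brain at day 50 at 0 UMIs and set to the floor) and Ly6c1 (2.11). Genes higher at day 14 and lower at day 50 included the receptor gene Il1r1 (-2.49), the activation genes Egr2 (-2.77) and Tnfrsf9 (-1.50), the cytokine genes Lta (-2.27) and Ccl1 (-1.59, with 98.2% of brain and 58.1% of spinal cord UMIs at day 50 in 2 cells each), and Bcl6 (-2.40). The linker histone genes Hist1h1b (-2.41) and Hist1h1e (-2.50), and Ermn (-1.73), Ly6g5b (-1.85) and Nrgn (-1.54), did the same. In brain at day 50, 2 cells held 43.9% of Hist1h1b UMIs. They held 35.7% of 14 UMIs for Bcl6, 33.3% of 12 for Egr2 and 35.0% of 20 for Ly6g5b. After the day 14 all-gene median is subtracted, Ccl1, Ermn, Hist1h1b, Nrgn and Tnfrsf9 fall short of 1.5-fold at day 14.

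Gzmk, Eomes and Ccl5 were higher at day 50 in both tissues, and led cluster 11, while cluster 9 was also led by Ccl5 and Gzmk. CD8 T cells or natural killer cells in the sort are argued against by Cd8a, Cd8b1, Ncr1 and Klrb1c, which together reached 8.60 CPM in cluster 11 and 9.86 CPM in the other cells of all libraries, or 8.44 and 6.62 CPM within the day 50 spinal cord, although Cd4 was detected in 25.4% of cluster 11 cells and 36.5% of other cells of the day 50 spinal cord. Doublets are argued against by a median UMI ratio of cluster 11 cells to their own library of 0.967. The library median includes the cluster's own cells. Within the day 50 spinal cord, cluster 11 cells held a median of 3357.5 UMIs and the other cells 3614. Free RNA spread over the day 50 spinal cord is argued against by cells with a Tmem176a or Tmem176b UMI, in which the 3 genes had a median log2 ratio of -3.97 (-4.58 to -3.46) to cells without; brain was not tested for it. A difference between single libraries, in disease phase, mice or handling, stays open as untested.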

How the results depend on the processing

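Leaving out the 2 richest cells per gene, leaving out the highest doublet scores and requiring Ashman's D above 2 were chosen after seeing the data; the other alternatives were planned and run. List medians here are given before an all-gene median is subtracted, and a cause is given only where stated.

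Residency kept its direction under every alternative in brain over time (0.092 to 0.46), in spinal cord over time (0.044 to 0.39) and for the tissues at day 14 (0.079 to 0.34), and immediate early and heat shock genes stayed lower in spinal cord at day 14 (-0.74 to -0.36) and at day 50 (-0.95 to -0.59). The main residency median in spinal cord over time, 0.11, had an interval that includes 0 (-0.037 to 0.22). So did that for the tissues at day 50, -0.03 (-0.17 to 0.23). Egress in brain over time stayed between -0.39 and -0.086. Of 1445 values for named genes under the alternatives, 1228 stayed within their interval, 214 moved and 3 reversed; of 936 other list medians, 822 stayed, 98 moved and 16 reversed. Some alternatives could move little. Leaving out cells with a Foxp3 UMI removed very few cells, and keeping Scrublet's calls left the day 14 libraries unchanged. The counts that stayed are therefore no measure of robustness. Cluster shares other than that of cluster 11 stayed in 33 of 132 and moved in 99, and shares of the focal transcripts stayed in 35 of 120 and moved in 85. The alternatives for focal transcripts change the UMIs per cell, which by itself changes detection. Cluster shares are those of the nearest cluster, which for some clusters shared few cells. For cluster 5 at resolution 0.5, cells in both over cells in either came to 0.060.

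Median-of-ratios scaling shifts every gene of a comparison by 1 factor, which is the cause of its changes. In spinal cord from day 14 to day 50 it gave residency 0.39 (from 0.11), egress 0.30 (from 0.02), TCR activation 0.037 (from -0.25), immediate early and heat shock 0.21 (from -0.07) and oxidative phosphorylation 0.14 (from -0.14). For the tissues at day 14 it gave residency 0.079 (from 0.29), egress -0.55 (from -0.34), TCR activation -0.088 (from 0.12), lipid handling -0.10 (from 0.12) and survival -0.15 (from 0.06). Totals without mitochondrial, ribosomal and receptor genes act the same way: residency 0.25, egress 0.16, immediate early and heat shock 0.070 in spinal cord over time, and survival -0.023 for the tissues at day 14. The oxidative phosphorylation median, day 50 against day 14 in spinal cord, was 0.0037 that way. The mean of cells gave residency 0.23 in spinal cord over time; the cause was not tested.

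Thinning cells to 2000 UMIs before summing gave, in spinal cord over time, egress -0.39, interferon response -0.023 (from 0.08) and immediate early and heat shock 0.019, and at day 14 egress -0.19 and regulatory T cell genes 0.16 (from -0.44); the cause was not tested. At 1000 genes and 5% mitochondrial UMIs, egress at day 14 was -0.24, and the cause was not tested. Without cycling cells, proliferation of spinal cord against brain was 0.080 at day 14 (from -0.39) and 0.093 at day 50 (from -0.44), which the removal of the cells that carry those genes brings about. Without the 2 richest cells per gene, residency in brain over time was 0.092 (from 0.20), Tfh -0.012 (from 0.70) and Cd74 -1.09 (from 2.5), and in the tissues at day 50 proliferation was 0.29 (from -0.44), Ube2c 1.15 (from -3.05) and Cd74 0.25 (from -2.98). For Cd74 and Ube2c those cells held most UMIs in the day 50 brain library. Leaving out 2 of 333 cells weighs more than 2 of 10313, and the all-gene median itself went from -0.058 to -0.35 in brain over time and from 0.028 to 0.21 for the tissues at day 50; beyond that the cause was not tested.

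The share positive for all 3 antibodies, in the order brain day 14, spinal cord day 14 and spinal cord day 50, was 5.74%, 21.8% and 12.8% with 1 gate over all libraries, 2.72%, 7.36% and 21.0% with gates raised by 0.5 on the log scale and 18.9%, 33.3% and 44.5% with gates lowered by 0.5. With Ashman's D above 2 required, 6 of the 9 gates pass and the share can be given in 1 library of 3, spinal cord at day 50. The joint share of Cd69, Cxcr6 and P2rx7 transcripts, which falls with fewer UMIs per cell, was 0.312% in brain at day 14, 0.612% in brain at day 50, 0.605% in spinal cord at day 14 and 0.502% in spinal cord at day 50 at 1000 UMIs, and 6.17%, 5.41%, 12.4% and 5.42% without thinning. The share of the cluster nearest to cluster 11, in the order brain day 14, brain day 50, spinal cord day 14 and spinal cord day 50, was 6.59%, 42.3%, 0.248% and 59.0% at resolution 0.5, 0.630%, 29.7%, 0.183% and 44.5% at resolution 1.5, and 8.58%, 16.2%, 6.33% and 21.9% after centring per library. At resolution 0.5 the same cluster was also the nearest to cluster 3, so its shares are not those of cluster 11 alone. The cause of the other changes was not tested.

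Depth limits the day 50 brain library most: its floor is 2.69 CPM against 0.0635 CPM at day 14.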

Other observations

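The test of heat shock genes, the cluster test and both antibody depth tests were chosen before the result was seen, and a condition added afterwards to the heat shock test is described with it; the genes farthest from 0 in the triple-positive cells were chosen after the data were seen.

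Beyond the focal genes, some of the genes farthest apart between triple-positive and triple-negative cells were shared by the 3 libraries with gates and others were not. In brain at day 14 the positive cells were richest in the Th17 cytokine genes Il17f (13.6-fold, which rests on 1 cell with 489 of its 855 UMIs) and Il22 (6.49-fold) and in Tff1 (5.34-fold), which encodes a trefoil peptide of mucosa. In spinal cord at day 14 they were richest in Tff1 (13.7-fold) and in Ly6g5b (6.05-fold), and held less Gzmb (log2 -4.03) and Cd27 (-3.27). In spinal cord at day 50 the genes farthest above 0 by their interval were instead Plac8 (13.6-fold) and Ly6c2 (13.4-fold), with Itga1, the collagen-binding integrin gene, also high (log2 5.39, interval 2.89 to 10.71, over 1 UMI in the negative cells). Tmem176a and Tmem176b, both on the Th17 list, were among the genes farthest from 0 in all 3 libraries, at 4.33-fold and 4.20-fold in brain at day 14, 4.75-fold and 4.02-fold in spinal cord at day 14 and 12.5-fold and 11.3-fold at day 50. The chemokine genes Ccl3 (-6.93, interval -12.26 to -4.38, over 1 UMI in the positive cells) and Ccl4 (-3.62) were lower in the positive cells of the day 50 spinal cord.

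Other lists also differed within libraries between positive and negative cells. Proliferation genes were higher in 15 of 26 members in brain at day 14 (median 0.68) and in 15 of 26 in spinal cord at day 14 (0.85), but in 0 of 17 at day 50 (-0.39, 3 lower). The cycling cells of cluster 1 had a median UMI ratio of 2.05 to their own library, and the gates used unscaled antibody counts. Whether richer cells passed the gates more easily was not tested. Glycolysis had medians of 0.42, 0.39 and 0.42 in the order brain day 14, spinal cord day 14 and spinal cord day 50, and Tfh genes of -0.53, -1.44 and -1.31. Effector cytokines and chemokines had medians of 0.83, 0.65 and 0.25, and Th1 genes of 0.17, 0.14 and 0.66.

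Before an all-gene median is subtracted, as for all ratios of this paragraph, the 11 immediate-early genes without heat shock members had lower medians in spinal cord than in brain at both days, of -0.75 at day 14 (7 lower) and -1.08 at day 50 (9 lower). A different make-up of clusters at day 14 is argued against for the 8 clusters tested. In them the median ratio lay between -0.89 and -0.10 with every interval below 0, and their median was -0.62. Cluster 4, led by such genes, was left out, and clusters 3, 5 and 11 had fewer than 100 cells in a day 14 library. Of these, cluster 3, with Junb among its leading genes, held 1387 brain and 74 spinal cord cells at day 14. Handling stress that raises heat shock genes stays open. Their median was -0.13 at day 14 (-0.16 to -0.09) and 0.16 at day 50 (0.01 to 0.28, 4 of 6 genes measured). The bound written beforehand against it, an interval above 0 at 1 of the days, was met at day 50. Subtracting the all-gene median of 0.028 would undo that. Members went both ways at day 14 (Hspa1a -0.99 and Hsph1 0.89). At day 50 Hspa8 stood at 0.30, and the interval of Hsph1 (-0.58, interval -1.15 to 0.021) included 0. The only interval below 0 at day 50 was that of Hspa1a (-9.73 to -0.38), which had too few UMIs to be compared. The condition that members going both ways decide nothing was added after those values were seen. At day 50 it was met from below only by Hspa1a. A tissue difference in recent stimulation was not tested.

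The share of triple-positive cells in spinal cord was higher at day 50 with gates per library and lower with 1 gate. A lower mean antibody count alone did not give the first order. Day 14 counts thinned to the day 50 mean and gated again gave 16.8% (16.0 to 17.6) against 30.8% (28.5 to 33.1) at day 50. The gates fitted to the thinned counts were 7.12, 8.60 and 7.48 for CD69, P2X7 and CXCR6. Those at day 50 were lower, at 4.03, 5.30 and 4.36. How much of the first order comes from these lower gates was therefore not decided by the thinning. The second order is consistent with lower antibody depth at day 50, since at equal mean counts and 1 gate the day 50 share was 20.9% (19.0 to 23.0) against 15.4% (14.7 to 16.2). Equal means also remove any real difference in mean staining, and under the stricter separation rule the day 14 library has no triple gate, so which order holds in the tissue stays open.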
